A study of Mus musculus with 4 samples.

How the data were processed

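Ribosome profiling sequences the short RNA fragments that ribosomes protect from nuclease digestion, so that the number of fragments on a gene reflects both how much of its mRNA is present and how densely that mRNA is occupied by ribosomes. The series holds 4 such libraries from MLE-12, a mouse lung epithelial cell line immortalised with the SV40 large T antigen and used as a model of alveolar type 2 cells. Control cells (replicates 1 and 2) are compared with cells given 5 µM 1-nitropyrene, a nitrated polycyclic aromatic compound of diesel exhaust (replicates 2 and 3). There is no 1-nitropyrene replicate 1 among the 4 libraries, and whether any library was left out of the series cannot be told from the labels. Per the series' design text the exposure lasted 12 h. Per the labels' protocols the cells were washed with cycloheximide, which holds ribosomes in place, footprints were purified with a commercial kit, ribosomal RNA was depleted and libraries were built with a small RNA kit. Nothing in the labels says that the 2 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

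The authors deposited 1 table of whole-number footprint counts per gene, with no normalization, for 53465 Ensembl mouse gene IDs and 1 column per library; it has 0 other sample columns and 0 lines without a gene ID. Per the submitters' processing notes the tools were cutadapt, Bowtie, HISAT2, featureCounts and DESeq2 and the genome build was mm10. Their versions, roles and settings, the gene annotation, any selection of fragment length, and how reads matching several genes or the antisense strand were counted are not given in the sources used here. Counts of genes that share sequence with a near-identical copy, overlap another gene or have an antisense partner are therefore uncertain, and these genes could not be picked out by ID.

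The count table pairs no symbols with its IDs. The gene table used here, of assembly GRCm38.p6, lists 49997 genes and gives an Ensembl ID for 0 of them, so 0 of the IDs could be matched to a symbol, and no name was inferred from an ID. For this reason the planned look-up of Fbxw7 and Alkbh5, the planned tests of 31 lists of gene symbols (stress responses, senescence, m6A and SUMO machinery, fibrosis, lung cell type markers and others), and the planned removal of mitochondrial and small RNA genes were not run, and these genes are not analysed here. Translational efficiency needs RNA libraries of the same cells, which are not analysed here, so every value below is a level of counted fragments, called footprints. As small RNA genes were not removed and no length selection is known, some counts may come from fragments that no ribosome protected.

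Total counts were 1261372 and 1136145 in control replicates 1 and 2, and 1243186 and 1357034 in 1-nitropyrene replicates 2 and 3. After scaling, 1 count was worth 0.761, 0.844, 0.860 and 0.792 CPM (counts scaled to a library of 1e6) in these libraries, and a count of 0 allows a level of up to 3 counts, or 2.28, 2.53, 2.58 and 2.38 CPM. Such limits cover counting error only.

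Genes were kept with edgeR's filterByExpr at its default settings (minimum count 10, minimum total 15), which left 7719 IDs holding 98.6% of the counts. Libraries were scaled with TMM, and 1-nitropyrene was compared with control by edgeR's quasi-likelihood F test (R 4.3.3, edgeR 4.0.16) with no covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The estimated prior degrees of freedom were infinite, so every gene took its spread from the trend over genes of like abundance. Standard errors of log2 fold changes were derived from the fold change and the F statistic. The rule for naming genes, fixed before the data were examined, ranked called genes by fold change among those with a mean count of at least 50 and groups that do not overlap; its condition on symbols could not be applied, and since the IDs carry no names only the first 2 in each direction are printed.

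As no list of symbols could be used, 3 sets of Ensembl IDs were taken after the data had been seen from the mouse cell cycle marker pairs shipped with scran 1.30.0. For each phase, the pairs in which an ID was the lower member were subtracted from those in which it was the higher member. The ID was put in the phase with the largest difference, if that was at least 10. The sets were tested with limma's camera (limma 3.58.1) on voom values at its preset correlation of 0.01, with an estimated correlation and with fry as alternatives, adjusted over the 3 sets.

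The alternatives were DESeq2's size factors, total counts, no filter, a filter of 5 CPM in 2 libraries, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, added fold thresholds of 1.5 and 2, and leaving out each library. Leaving out the 2 IDs with the most counts, DESeq2 on the same genes as edgeR, and counting only calls with a mean count of 50 or more were added after the data had been seen. All 3 tools were tested on simulated counts with the real means, library sizes and edgeR's trended dispersion for the 7719 genes, 200 of them changed, which were drawn from genes with a mean count of at least 10. For 50 such genes each changed 1.5-, 2-, 3- and 4-fold, edgeR recovered 26%, 56%, 84% and 84%, DESeq2 10%, 42%, 68% and 66%, and limma-voom 20%, 54%, 74% and 70%. Calls among the unchanged genes numbered 4, 0 and 3. With no gene changed, they numbered 0, 0 and 2. Since the simulated spread was edgeR's own estimate, these shares do not decide between the tools on the real counts.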

Results

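Ribosome footprints were counted per gene in 4 libraries of MLE-12 mouse lung epithelial cells, 2 from control cells and 2 from cells given 5 µM 1-nitropyrene for 12 h. The series asks how the compound acts on translation, of the ubiquitin ligase receptor gene Fbxw7 in particular, but the IDs of the count table could not be tied to symbols, so no value is given for Fbxw7. The control libraries held 1261372 and 1136145 counts and the 1-nitropyrene libraries 1243186 and 1357034. Of the 53465 gene IDs, 13738 had a count in any library. Control libraries detected 12041.5 ± 169 IDs and 1-nitropyrene libraries 11786.5 ± 57.3 (SD, n = 2 each). With 2 libraries per group, an exact two-sided permutation test of any single value cannot go below p = 0.333.

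A pair of gene IDs took 29.7% ± 0.0636 of all counts in control cells and 32.9% ± 0.0963 in 1-nitropyrene cells (SD, n = 2 each). Neither ID could be named, so whether these counts come from translated genes is not known. The ID with the most counts rose from 16.0% ± 0.0255 to 19.3% ± 0.0403 of the library, a 1.35-fold increase after TMM scaling (log2 fold change 0.43 ± 0.0076 SE). The ID with the second most counts held 13.7% ± 0.0380 and 13.6% ± 0.0559, so that it was slightly lower as a share of all counts but 1.11-fold higher after TMM scaling. The ID next in rank fell from 1.77% to 1.23% of the counts, to 0.781 of its control level after TMM scaling (edgeR quasi-likelihood test, adjusted p = 2.36e-83). Outside the leading pair, 887260 and 798153 counts remained in the control libraries and 834409 and 908975 in the 1-nitropyrene libraries.

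The libraries were compared pairwise to see whether any had been deposited more than once. Over genes with at least 20 counts in the pair, the chi-square statistic per degree of freedom was 1.55 between the controls and 1.61 between the 1-nitropyrene libraries. No library was thus taken as a copy of another, and each was counted as a sample. The statistic cannot tell separate cultures from repeat libraries of the same culture. Across groups it lay between 5.82 and 6.02 in the 4 pairs. The statistic takes reads as independent molecules and covers counting error only. Pearson's correlation of log2 CPM across genes was 0.962 within either group and 0.925 to 0.931 between groups; genes are not independent replicates.

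Footprint levels differed between 1-nitropyrene and control cells for 1332 of the 7719 genes tested (17.3%), of which 747 were higher and 585 lower in the 1-nitropyrene libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small. The median called increase was 1.55-fold and the median called decrease 1.82-fold, while 182 of the genes that rose and 222 of those that fell changed at least 2-fold. Lower calls lay more among scarce genes, where small changes are seldom called, so these values do not compare the size of rises and falls. The libraries of the 2 groups did not overlap in CPM for 746 of the genes that rose and 583 of those that fell; among all genes tested 57.3% did not overlap, against 33.3% by chance for 2 against 2. The DESeq2 Wald test called 315 genes, 238 higher and 77 lower, all of them among the 1332 with the same direction. Scaling to total counts, which moved the median log2 fold change of the tested genes from -0.0076 to -0.17, called 406 genes higher and 1110 lower. The share of higher genes among the calls was thus 56.1% with TMM and 26.8% with total counts. Without control replicate 1 the count was 765, without control replicate 2 it was 742, without 1-nitropyrene replicate 2 it was 572 and without 1-nitropyrene replicate 3 it was 834.

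**Figure D1:**
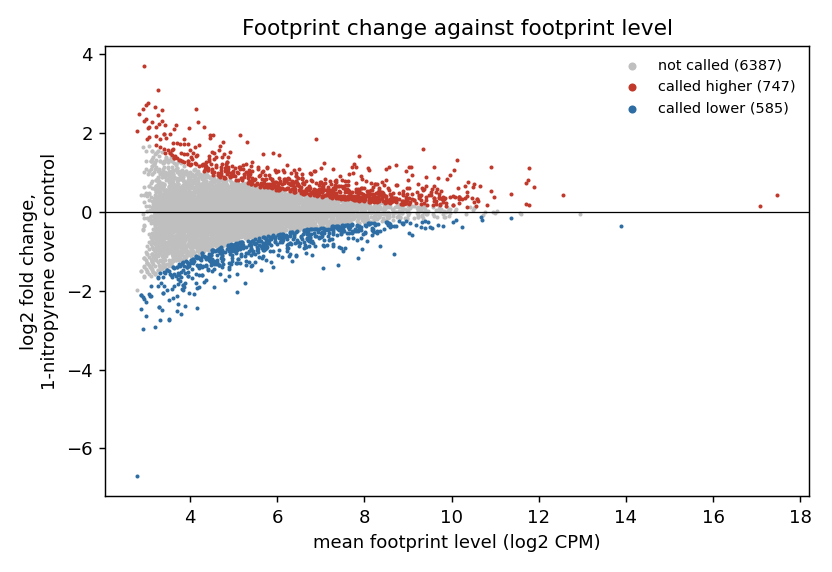
Log2 fold change of footprints (1-nitropyrene over control, TMM scaling) against mean footprint level in log2 CPM for the 7719 genes tested, with 1 point per gene and n = 2 libraries per group. Genes called higher (747, red) and lower (585, blue) lie outside a grey band that narrows with footprint level. The point at -6.70 is a gene with no count in either 1-nitropyrene library, at least 8.4-fold lower. This bound takes 3 counts over the group's 2 libraries together as the floor, and the gene's fitted value depends on the prior count.

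**Figure D2:**
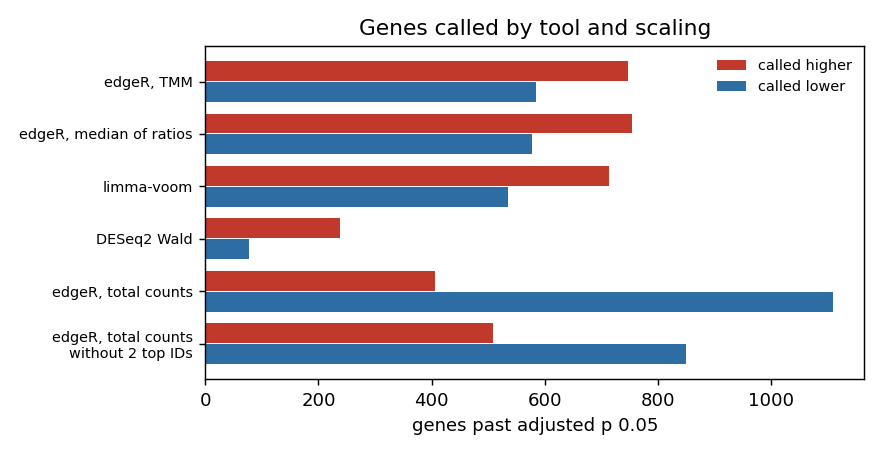
Number of genes past an adjusted p of 0.05 that were higher (red) or lower (blue) in 1-nitropyrene cells, by tool and scaling. Higher calls outnumber lower ones with TMM, median-of-ratios scaling, limma-voom and DESeq2, and lower calls outnumber higher ones under both total-count scalings.

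Of the called genes with a mean count of at least 50 and groups that did not overlap, 568 rose and 327 fell. The 12 with the strongest increases rose between 2.29- and 3.60-fold and the 12 with the strongest decreases fell between 2.23- and 2.77-fold, with adjusted p of at most 6.43e-05 and 7.69e-05 (edgeR quasi-likelihood test).

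ENSMUSG00000110549 rose the most in this set, from 51.2 ± 0.356 to 184 ± 17.2 CPM (SD, n = 2 each; edgeR log2 fold change 1.85 ± 0.17 SE, adjusted p = 3.32e-26). Its counts were 67 and 61 in the control libraries and 200 and 248 in the 1-nitropyrene libraries. ENSMUSG00000026193 rose from 325 ± 15.3 to 976 ± 60.6 CPM (SD, n = 2 each; edgeR log2 fold change 1.59 ± 0.067 SE, adjusted p = 6.82e-117), and is the more deeply covered of the pair, with 441 and 372 counts against 1184 and 1178. ENSMUSG00000099583 fell by 1.47 on the log2 scale (SE 0.26, edgeR adjusted p = 3.86e-07), from 69.4 ± 15.8 to 25.0 ± 4.95 CPM (SD, n = 2 each). It rested on 106 and 69 counts in the control libraries and 25 and 36 in the 1-nitropyrene libraries. ENSMUSG00000021025 fell by 1.43 on the log2 scale (SE 0.15, edgeR adjusted p = 1.42e-18), from 191 ± 16.8 to 70.5 ± 0.0464 CPM (SD, n = 2 each), with 235 and 240 counts against 82 and 89. The DESeq2 Wald test gave no adjusted p for ENSMUSG00000099583 with its own filter on low counts, and 0.0036 on the genes edgeR tested.

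**Figure D3:**
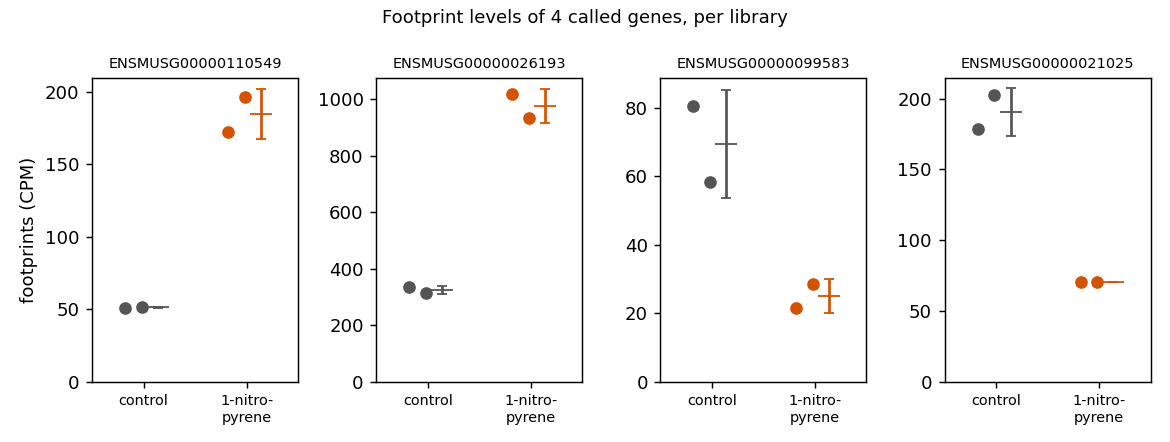
Footprint levels in CPM (TMM scaling, axes from 0) of the 4 printed gene IDs, with 1 point per library and the mean ± SD of each group's 2 libraries beside the points. In each panel the 2 groups do not overlap, which the rule that chose these IDs required. The control means are 51.2, 325, 69.4 and 191 CPM and the 1-nitropyrene means 184, 976, 25.0 and 70.5 CPM.

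The direction of the calls differed with footprint level. The tested genes were divided by mean level into 4 bins of equal size. In the most abundant bin (mean counts from 91.75 up), 477 rose and 225 fell, so that 67.9% of the calls were higher. In the least abundant bin (mean counts 6.5 to 19.25), 66 rose and 97 fell, or 40.5% higher. The next bins up had 80 higher and 118 lower calls, and 124 higher and 145 lower. The split differed between the most and the least abundant bin (Fisher's exact test over genes, two-sided, p = 1.65e-10; genes are not independent replicates). The median log2 fold change climbed from -0.12 in the lowest bin through -0.073 and -0.0073 to 0.082 in the highest. With total counts the calls were 35.1% higher in the highest bin and 21.3% in the lowest, so the majority turned in the highest bin. A change of scaling shifts all genes nearly alike and is no test of the difference between bins. More genes were called where coverage was deeper, 36.4% of the highest bin against 8.45% of the lowest.

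**Figure D4:**
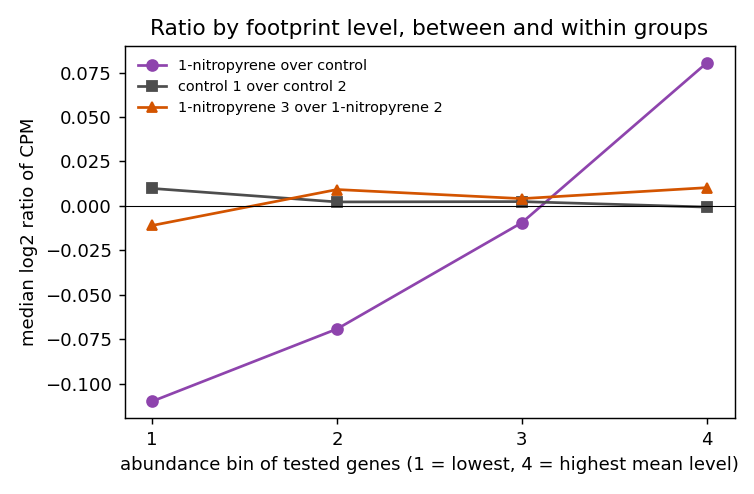
Median log2 ratio of CPM (TMM scaling, prior count 2) in each of 4 equal bins of the tested genes by mean footprint level, for the 2 groups and for the 2 libraries within each group. The ratio of 1-nitropyrene to control runs from -0.11 in the lowest bin to 0.081 in the highest, while the 2 ratios within groups stay between -0.011 and 0.010.

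Cell cycle genes were examined because the series concerns senescence, a lasting arrest of the cell cycle. No phase passed the camera test as a set. The G1 set had 160 tested members, of which 15 rose, 19 fell and 126 did not pass the test; the S set had 97, of which 4 rose, 7 fell and 86 did not pass; the G2M set had 119, of which 14 rose, 4 fell and 101 did not pass. Adjusted over the list alone, the calls were 17 higher and 21 lower in G1, 4 and 6 in S, and 14 and 4 in G2M. The median log2 fold change, relative to the other tested genes, was -0.040 in G1 (95% bootstrap interval over genes -0.098 to 0.020), -0.047 in S (-0.12 to 0.053) and 0.10 in G2M (-0.015 to 0.17). The camera test gave an adjusted p of 0.497 for each set, and an adjusted p = 0.529 for each with an estimated correlation. The fry test, which asks whether a set's own genes move one way on balance, gave adjusted p of 0.0939, 0.167 and 0.0664 for G1, S and G2M. For change in either direction it gave adjusted p of 0.0013, 0.0011 and 0.0049; that test is against no change in any member, and the called shares of 21.3%, 11.3% and 15.1% in G1, S and G2M lay around the 17.3% of all genes tested. These sets were derived from mouse embryonic stem cells and chosen after the data had been seen, and they were not matched with the other genes for abundance.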

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

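TMM and DESeq2's size factors, no filter or a stricter one, limma-voom, and TMM without the 2 IDs with the most counts kept the total, higher and lower counts within 1.5 times of 1332, 747 and 585. Total counts gave 406 higher and 1110 lower genes, and total counts without those 2 IDs 508 and 849. The DESeq2 Wald test called 315 genes (238 higher, 77 lower), and 345 (243 higher, 102 lower) on the genes edgeR tested without independent filtering, so that filter does not account for the gap. As a coefficient of variation, the median of DESeq2's dispersions per gene was 25.1% and the median of edgeR's trend 12.3%. These are unlike measures, and whether they account for the gap was not tested. Requiring at least 1.5-fold left 835 genes, 411 of them higher, and an unadjusted p under 0.05 with at least 2-fold 605, of which 257 were higher and 348 lower. With mean counts of 50 or more, 327 were called lower. Leaving out 1 library, with the lone sample assumed to vary like the other group, gave 572 to 834 genes, 382 to 480 higher and 190 to 354 lower. The 4 printed IDs kept direction and call in all 51 combinations of an ID and an alternative that gave an adjusted p. There were 13 such alternatives per ID, or 12 for ENSMUSG00000099583, whose log2 fold change ranged from -1.69 to -1.21. The IDs were picked from these data as the strongest called genes with separate groups, so their stability says little about the other calls. No set of cell cycle IDs passed a test of movement in 1 direction, or changed its direction. This covers 36 combinations of a set and an alternative (12 alternatives per set). Their adjusted p ran from 0.0664 (fry) to 0.636 (camera). The fry test for change in either direction, which every set passed, is not among them. The G1 median was 0.0005 above the other genes without 1-nitropyrene replicate 2, against the sign of the test. No paired analysis was possible because the groups share only replicate number 2. The removal of mitochondrial and small RNA genes and the alternatives for Fbxw7 and the symbol lists were not run. In the lowest 2 of the 4 abundance bins, 8.45% and 10.3% of genes were called; of 50 genes per bin changed 2-fold in simulated counts, edgeR recovered 6%, 32%, 82% and 98% from the lowest bin to the highest, and whether fewer scarce genes changed was not tested.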

Other observations

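The count of other splits, the G2M test and the test of the leading pair of IDs were chosen only after the results were seen; the depth test was set before its values. Of the 3 splits of the 4 libraries into 2 and 2, only the real one called genes: it called 1332, and the highest of the others 0 with edgeR (44 and 39 genes at an unadjusted p under 0.05, 0 and 0 with DESeq2). Each other split puts a control and a 1-nitropyrene library in either group, so any difference between the real groups adds to the spread within them. Few calls are then likely from the design alone, and the 0 does not show that false calls are controlled. The real split was thus 1 of 3, and 3 splits are too few for a share under 0.05.

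The balance of higher and lower calls turned with the scaling, from 56.1% higher with TMM to 26.8% with total counts. With TMM it also turned when a fold threshold was added. At least 1.5-fold left 411 higher and 424 lower calls, and at least 2-fold left 182 and 222. A candidate explanation of the turn with scaling is the leading pair of gene IDs, whose share of the library grew from 29.7% to 32.9%. The median log2 fold change of the 7717 other genes was -0.0079 with TMM and -0.17 with total counts, a gap of 0.16, and -0.10 with total counts without the pair. A gap of 0.0968 (58.9% of the whole) was thus left, so the pair accounts for part of the difference and not for all of it. Without an added standard, whether total footprint output per cell changed stays open, and with it which scaling gives the true directions.

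The tilt of the fold changes with abundance is a pattern a biologist might follow up once the IDs are named. Its median log2 ratio of 1-nitropyrene to control was 0.19 higher in the most abundant bin than in the least abundant (bootstrap SD over genes 0.023). The 1-nitropyrene libraries together were 1.08 times as deep as the controls. A depth difference was argued against by the pairs within groups, which differed by factors of 1.11 and 1.09 in depth but by only -0.010 (bootstrap SD 0.019) and 0.0213 (bootstrap SD 0.020) between the same bins. A response of the cells and a difference in digestion or library preparation between the groups stay open as untested, since each group may have been handled separately and no label gives a batch.

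Among called G2M-associated IDs, 77.8% were higher, against 55.8% of the other called genes. The hypothesis that they rise more often may hold, but Fisher's exact test over genes gave a two-sided p of 0.0918 (0.228 after adjustment over the 3 sets), which leaves it open. The G2M set was not matched with the other genes for abundance. Among all calls, 40.5% were higher in the least abundant bin and 67.9% in the most abundant. Whether abundance alone gives the G2M excess was not tested. The camera test (limma) of all 119 members gave an adjusted p of 0.497 at a median shift of 0.10, whereas a shift of 0.1 put into simulated counts in which no other gene changed passed an unadjusted threshold of 0.05. When a shift of 0.1 was added to the measured values of 100 random sets of 119 genes, 11 passed an unadjusted p of 0.05, against 55 with 0.2, 97 with 0.3 and 2 with none, so a shift of that size would usually be missed here.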
